A study of Rattus norvegicus with 15 samples.

How the data were processed

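RNA-seq had been run on total RNA, extracted with Trizol per the labels' protocols, from primary rat temporomandibular joint chondrocytes in 15 libraries. Each library was placed in its group by the treatment given in the labels: control, mechanical stress, control siRNA, Ddx5 siRNA, and Ddx5 siRNA with mechanical stress, with 3 libraries in each. The control's label does not say what the cells received, and it was taken as a control without siRNA because a control siRNA group stands beside it. The labels give the same replicate numbers in each group. How the stress was applied, for how long, and how the siRNA was delivered are not given in the sources used here. The series' design text says that the expression changes downstream of DDX5 were sought.

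The authors deposited a table of raw read counts per gene, with 1 column per library and no pooling of replicates, in which the file pairs each gene's identifier with a name, position, exonic length and biotype. The aligner, the counting tool, whether counting used strand, the genome build and the annotation release are not given in the sources used here, so coordinates are printed as deposited, without a build, and reads shared between close paralogs or overlapping genes could not be told apart. The table holds 33718 loci, of which 32545 have a name and 1173 do not, and 12068 have no count in any library. Total counts per library ran from 14309170 to 16219912, at which 3 counts correspond to 0.21 CPM (counts scaled to the library total) in the library with the lowest total. The authors also deposited FPKM values. These equal the count divided by gene length and by 1 number per library (largest relative deviation 5.2e-15), and that number is proportional to the library's median-of-ratios size factor, so the FPKM values carry another scaling than the one used here and no other reads.

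Tests used the counts as deposited. Genes with low counts were removed with filterByExpr by group, which left 14142. Libraries were scaled by the trimmed mean of M values (TMM), and edgeR 4.0.16 in R 4.3.3 fitted all 15 libraries with a term for each group, so that the groups shared the estimate of the spread. The quasi-likelihood F test with robust estimation was applied to each comparison, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes were not shrunk, and their SE was taken from the fold change and the F statistic. The common biological coefficient of variation was 0.217. Values per group are CPM on TMM-scaled library sizes, as mean ± SD over 3 libraries. The 7 comparisons were stress against control, Ddx5 siRNA against control siRNA, Ddx5 siRNA with stress against stress, Ddx5 siRNA with stress against Ddx5 siRNA, the difference between both stress effects, the difference between both Ddx5 siRNA effects, and control siRNA against control. For Ddx5, CPM was also compared by a two-sided exact permutation test, which for 3 libraries against 3 gives no p below 0.10.

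The 31 gene lists had been written out before the data were examined, as had the tests, the alternatives and the rule for named genes. Of their 615 symbols, 588 matched a gene name in the table, 7 matched through an older symbol in a RefSeq gene table, and 20 did not match. The 27 lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 3) with a preset correlation between genes of 0.01, adjusted over lists within a comparison, and again with an estimated correlation. Counts of called members are given over all genes and adjusted over the list alone.

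Named genes were 16 preset genes, and per comparison the 10 that rose most and the 10 that fell most among called genes whose groups did not overlap, with a mean of at least 2 CPM in the higher group and no provisional symbol, of which the text gives some, and up to 4 members of each list with the lowest adjusted p. Adamts1, Dnajb9, Creld2, Cgnl1, Slc7a5 and the members called in a count of 5 or fewer were chosen after their values were seen, as were the genes named among the other observations. For the Ddx5 siRNA under stress, 1 called gene is not reported here.

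Replicates were compared before averaging. Libraries of a group correlated at 0.958 to 0.985 in log2 CPM, and differed by more than sampling noise in every pair (chi-square per degree of freedom 7.6 to 62.75), so none was counted as a repeat deposit. Whether shared replicate numbers pair the libraries was judged from the correlation of their deviations from the group means, with pairing taken where all 3 pairs exceeded 0.1. This held for stress against control (0.27 to 0.40) and for stress in cells with the Ddx5 siRNA (0.25 to 0.59). In the former 3 of 3 libraries correlated best with their own number, and in the latter 2 of 3. The blocked count of genes is given beside both comparisons, and other blocked values where they changed a call.

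The alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, a fit of only the groups compared, the replicate number as a block, each library left out in turn, and limma with a trended prior on log2(FPKM + 1) and log2(FPKM + 0.1) for genes at 0.5 FPKM or more in at least 3 libraries, or without that filter. Further alternatives were added after the data were seen: leaving out replicate 1 of both Ddx5 siRNA groups together, the control in place of the control siRNA, leaving out the 10 most abundant genes, fitting only the groups compared with the block, and leaving out libraries in the list tests and in the Ddx5 level.

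The scripts were tested on simulated counts drawn with the means and totals of the real libraries for 14142 genes, of which 200 were changed. For stress against control, edgeR recovered 16.4% of genes changed 1.5-fold, 50.7% of those changed 2-fold and 83.3% of those changed 4-fold, with 7 false calls among 107. DESeq2 recovered 26.9%, 64.2% and 93.9%, with 30 false calls among 153. For the difference between the stress effects edgeR recovered 5.97% at 1.5-fold, 34.3% at 2-fold and 66.7% at 4-fold, with 4 false calls among 75. A simulated list of 25 genes raised 1.5-fold was called, and 0 of 20 unchanged lists were. The simulated genes were drawn independently of each other, so this does not show how the list test behaves with correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.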

Results

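Gene expression was measured by RNA-seq of total RNA from primary chondrocytes, the cartilage cells of the joint surface, taken from the rat temporomandibular joint (the jaw joint). The 15 libraries fell into 5 groups of 3. One group was the control, whose label gives no further detail. It was taken to be without siRNA because a separate control siRNA group exists, and what these cells received is not stated. One group was exposed to mechanical stress. The other groups received a small interfering RNA (siRNA, a short RNA that triggers the degradation of a matching transcript). One received a control siRNA, one an siRNA against Ddx5, and one the Ddx5 siRNA together with mechanical stress. Ddx5 encodes a DEAD-box RNA helicase that acts in transcription and RNA processing. No group with the control siRNA and stress was among the samples, so the Ddx5 siRNA under stress was compared with stress without siRNA. The total count per library lay between 14309170 and 16219912, and 14142 of 33718 genes had enough counts to be tested. The labels do not say whether the 3 libraries of a group came from separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical.

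The targeted gene was examined first. Ddx5 (ENSRNOG00000030680, chromosome 10, 94980928 to 94988461, minus strand, coordinates as deposited with no build given) stood at 545.4, 510.6 and 485 CPM (read counts scaled to the library total) in the control libraries and at 397.2, 398.3 and 360 CPM in the control siRNA libraries. It was lower in each library with the Ddx5 siRNA, at 220.6, 251.7 and 206.8 CPM without stress and 164, 240.5 and 193.9 CPM with it. The stress libraries without siRNA held 360.3, 416.1 and 418.1 CPM. Ddx5 fell to 58.8% of the control siRNA level (log2 fold change −0.77, SE 0.13, edgeR adjusted p = 0.022, n = 3 per group). Under stress it fell to 50.1% of the level in stressed cells without siRNA (−0.997, SE 0.13, edgeR adjusted p = 0.014). The groups did not overlap in either comparison, for which a two-sided exact permutation test gives its smallest possible p, 0.10. The difference between stress and control (−0.37, SE 0.13) did not pass (edgeR adjusted p = 0.18, and 0.0055 in a fit of only these 6 libraries with the replicate number as a block), nor did that between control siRNA and control (−0.42, SE 0.13, edgeR adjusted p = 0.079). The knockdown call was lost without Ddx5 siRNA replicate 2 (edgeR adjusted p = 0.081) or 3 (0.15) or control siRNA replicate 1 (0.11), 2 (0.13) or 3 (0.068), and that under stress without stress replicate 3 (0.12) or Ddx5 siRNA plus stress replicate 3 (0.093). Ddx17, the closest paralog of Ddx5, averaged 110 ± 6.8 CPM with the control siRNA and 157 ± 18 CPM with the Ddx5 siRNA (SD, n = 3), a difference that did not pass over all genes (log2 fold change 0.51, SE 0.16, edgeR adjusted p = 0.15).

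**Figure D1:**
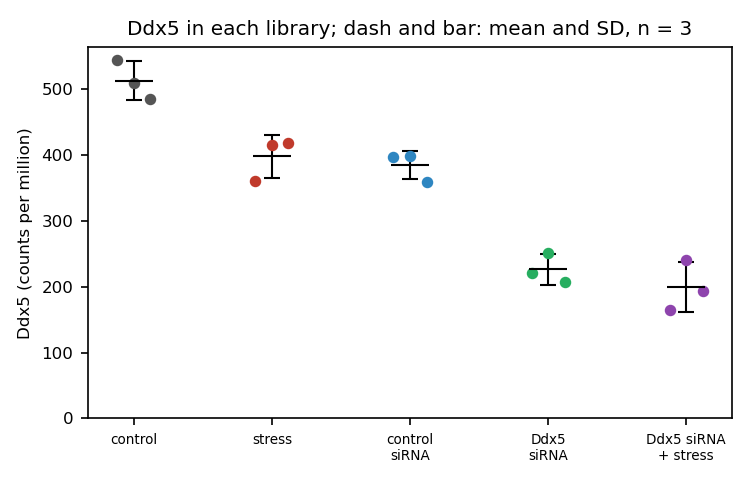
Ddx5 in CPM in each of the 15 libraries (points), with the mean and SD of each group of 3 (dash and bar). The 6 libraries with the Ddx5 siRNA lie between 164 and 251.7, and the other 9 between 360 and 545.4.

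To see what mechanical stress did to chondrocytes, the stressed cells were compared with the control. Inflammatory genes rose together. Of 28 measured inflammatory mediators and NF-kB targets, 14 rose and none fell (19 rose adjusted over the list alone), with a median log2 fold change of 0.83. Icam1, the leukocyte adhesion receptor (chromosome 8, 22035256 to 22047059), rose from 310 ± 42 to 816 ± 66 CPM (SD, n = 3; log2 fold change 1.40, SE 0.12, edgeR adjusted p = 3.3e-05). Nfkbia, which encodes an inhibitor of NF-kB that is itself an NF-kB target, rose by 1.15 (SE 0.12). The adhesion receptor Vcam1 rose by 3.19 (SE 0.32) and the neutrophil chemokine Cxcl2 (chromosome 14, 18731378 to 18733391) by 4.15 (SE 0.48), from 0.45 ± 0.14 to 8.13 ± 3.72 CPM. The list as a whole rose (camera adjusted p = 9.3e-22), and adjusted p = 0.00095 with an estimated correlation.

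Genes of glycolysis and the response to low oxygen also moved upward under stress. All 26 measured members had a positive log2 fold change (median 1.02), 9 rose over all genes and 22 rose adjusted over the list alone. Hk2, a hexokinase that starts glycolysis (chromosome 4, 113559427 to 113610243), rose from 36.4 ± 5.5 to 110 ± 21 CPM (SD, n = 3; log2 fold change 1.60, SE 0.25, edgeR adjusted p = 0.0069), a call lost without control replicate 1 (0.052). Pfkl, which encodes a phosphofructokinase subunit, rose by 1.71 (SE 0.26), and Kdm3a, a histone demethylase gene induced by hypoxia, by 1.15 (SE 0.16), and both kept their calls with any of the 6 libraries left out. The list passed with the preset correlation (camera adjusted p = 5.8e-21) but not otherwise (adjusted p = 0.35 with an estimated correlation).

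Of 20 measured matrix-degrading proteases, 4 rose and 1 fell under stress (5 rose and 1 fell adjusted over the list alone). The stromelysin genes Mmp3 (chromosome 8, 5676665 to 5698579) and Mmp10 (chromosome 8, 5734348 to 5742243) rose by 1.39 (SE 0.19) and 1.53 (SE 0.22) on the log2 scale. Mmp3 went from 57.1 ± 7.7 to 150 ± 15 CPM. The gelatinase gene Mmp9 rose by 1.82 (SE 0.32) and the collagenase gene Mmp13 (chromosome 8, 5522739 to 5533018) by 2.96 (SE 0.62), the latter from 0.43 ± 0.14 to 3.41 ± 0.33 CPM. The aggrecanase gene Adamts1 fell by 0.86 (SE 0.20). Adamts4 and Adamts5, which encode the other main aggrecanases, did not pass (log2 fold changes of 1.18, SE 0.57, and 0.42, SE 0.39), but did when only these 6 libraries were fitted with the replicate block (edgeR adjusted p = 0.0037 and 0.043). The list passed with the preset correlation (camera adjusted p = 0.048; adjusted p = 0.77 with an estimated correlation) and was lost without control replicate 3 (0.26) or stress replicate 1 (0.061) or 2 (0.072). The Mmp9 call was lost without control replicate 1 (edgeR adjusted p = 0.069), 2 (0.078) or 3 (0.066) or stress replicate 1 (0.071), and the Adamts1 call without control replicate 1 (0.21) or 2 (0.15) or stress replicate 1 (0.17), 2 (0.12) or 3 (0.13). The Mmp13 call was lost without control replicate 1 (edgeR adjusted p = 0.15), 2 (0.076) or 3 (0.094) or stress replicate 1 (0.092) or 2 (0.077).

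Chondrocyte genes gave fewer calls. Most of the cartilage matrix and identity list was low. Its 26 matched genes, tested or not, had a median of 2.2 CPM in the control and 2.6 CPM under stress. For fibroblastic matrix genes these medians were 1359 and 1285 CPM, so low counts limit what the cartilage list can show. Of 17 measured cartilage matrix and identity genes, 1 passed: Sox9, the transcription factor that sets chondrocyte identity (chromosome 10, 101288489 to 101293379), fell from 20.5 ± 1.6 to 10.9 ± 1.9 CPM (log2 fold change −0.92, SE 0.21, edgeR adjusted p = 0.048). Acan, which encodes the main cartilage proteoglycan, did not pass (−0.45, SE 0.38; edgeR adjusted p = 0.021 with only these 6 libraries and the replicate block). The list had a median log2 fold change of 0.05, a mean of −0.07 and a downward camera direction that did not pass (adjusted p = 0.77). Runx2, a regulator of chondrocyte hypertrophy, fell by 0.61 (SE 0.13, edgeR adjusted p = 0.032), the only call among 12 hypertrophy and mineralization genes (2 fell adjusted over the list alone). The Sox9 call was lost with any of the 6 libraries left out (edgeR adjusted p from 0.084 without control replicate 3 to 0.15 without control replicate 1). The Runx2 call was lost without control replicate 1 (0.076), 2 (0.088) or 3 (0.099) or stress replicate 1 (0.16) or 3 (0.088). Id3 and Id4, inhibitors of DNA binding by helix-loop-helix factors and targets of BMP signalling, fell by 0.97 (SE 0.14) and 1.13 (SE 0.17) and kept these calls with any library left out.

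Among the other lists under stress, splicing factors had 1 member that fell of 27 (Srsf6, −0.42, SE 0.07; 3 fell adjusted over the list alone) and a downward camera call (adjusted p = 7.2e-05; adjusted p = 0.35 with an estimated correlation). Piezo1, a stretch-gated channel gene, rose by 0.64 (SE 0.14) and Cav1, a caveola coat gene, fell by 0.60 (SE 0.11), and the 18 mechanosensor genes as a list did not pass (camera adjusted p = 0.99). The Piezo1 call was lost without control replicate 1 (edgeR adjusted p = 0.12) or 3 (0.082) or stress replicate 1 (0.13) or 2 (0.12), and the Cav1 call without control replicate 1 (0.062) or stress replicate 1 (0.065) or 2 (0.062). The 22 cholesterol synthesis genes did not pass either (camera adjusted p = 0.099, and 0.025 downward with the replicate block). Markers of other cell types did not pass as lists (camera adjusted p = 0.71 for macrophages and leukocytes, 0.67 for skeletal muscle, 0.99 for synovial fibroblasts and tendon and 0.95 for Schwann cells and neurons). Of the skeletal muscle markers 1 fell, Myh1, by 0.81 (SE 0.16), a call lost without control replicate 1 (0.079) or stress replicate 2 (0.077) or 3 (0.065).

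In total 199 genes passed for stress in edgeR's quasi-likelihood test, 150 higher and 49 lower, 78 of the former and 10 of the latter by at least 2-fold. With the replicate number as a block, which the libraries of these groups bear out, 366 passed, 264 higher and 102 lower, and 1682 when only these 6 libraries were fitted with the block, 941 higher and 741 lower (55.9% higher, against 75.4% without). The count was 81 without control replicate 1, 117 without control replicate 2, 121 without control replicate 3, 84 without stress replicate 1 and 94 without stress replicate 2. The genes that rose most included the lipoprotein lipase inhibitor gene Angptl4 (from 4.0 ± 3.2 to 134 ± 54 CPM), whose call was lost with any of the 6 libraries left out (edgeR adjusted p 0.052 without stress replicate 3 to 0.12 without control replicate 2), the chemokine genes Ccl5 and Cxcl3 (by 4.15 and 3.29) and the growth factor gene Csf2 (by 2.96), which kept theirs.

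**Figure D2:**
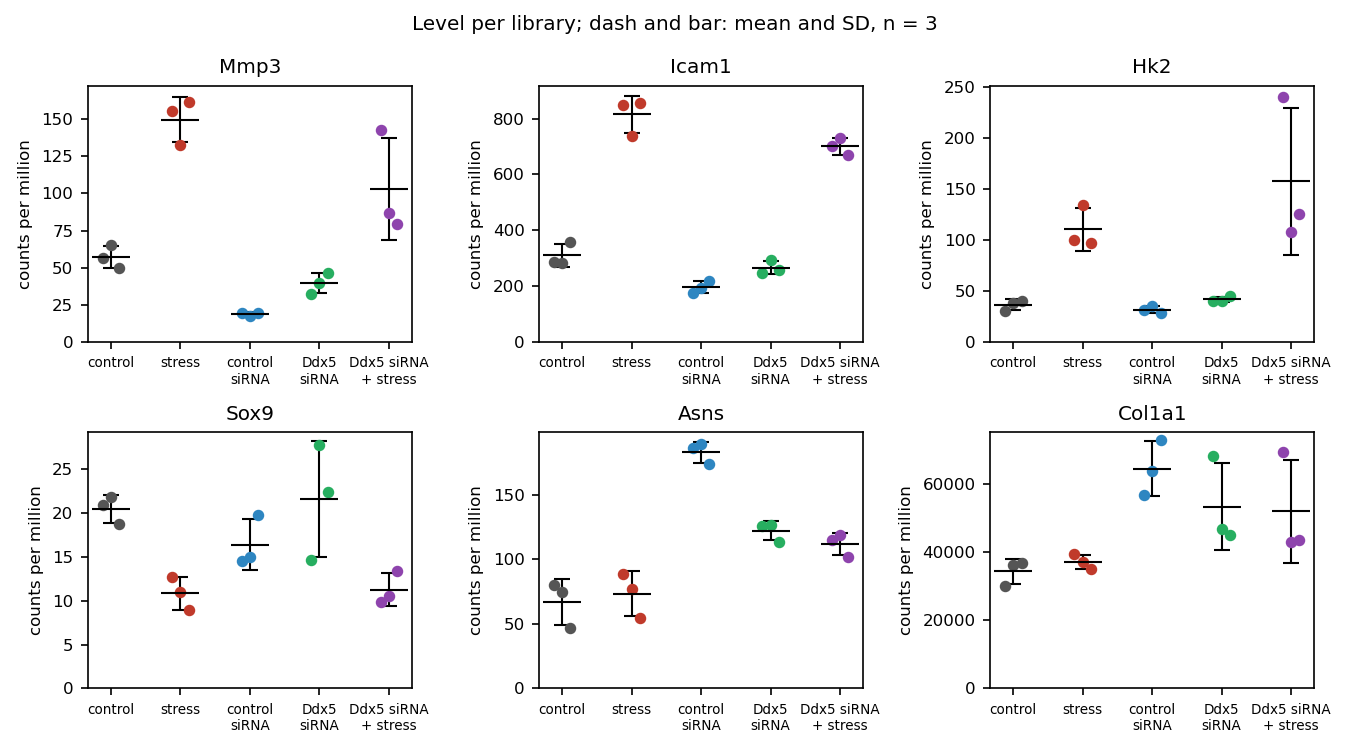
CPM of 6 genes in each library (points), with the mean and SD of each group of 3 (dash and bar). Mmp3, Icam1 and Hk2 were higher and Sox9 was lower in both stressed groups than in the unstressed group of the same siRNA status, and Asns and Col1a1 were highest on average with the control siRNA.

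The stress response was next examined in cells with the Ddx5 siRNA. Inflammatory genes again rose as a list, with 16 of 28 higher (20 adjusted over the list alone), a median log2 fold change of 1.13 and 28 positive values (camera adjusted p = 5.3e-32; adjusted p = 0.00017 with an estimated correlation). Icam1 rose by 1.40 (SE 0.12) and Nfkbia by 1.75 (SE 0.12). Cxcl2 rose by 4.84 (SE 0.48), from 0.48 ± 0.21 to 14.1 ± 1.2 CPM. Of the 26 glycolysis and hypoxia genes 8 rose (21 adjusted over the list alone) and all had positive values. Hk2 rose by 1.92 (SE 0.25) and Kdm3a by 1.41 (SE 0.16). That list passed with the preset correlation (camera adjusted p = 2.3e-23) and not with an estimated one (adjusted p = 0.33 with an estimated correlation).

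The proteases Mmp3, Mmp10 and Mmp9 rose by 1.38 (SE 0.19), 1.72 (SE 0.23) and 1.89 (SE 0.33) when stress was added to the Ddx5 siRNA, and they were the only calls among 20 proteases (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.15). Mmp3 went from 39.4 ± 6.8 to 103 ± 35 CPM. The Mmp9 call was lost without Ddx5 siRNA replicate 2 (edgeR adjusted p = 0.090) or 3 (0.076). Mmp13 did not pass (2.44, SE 0.59, edgeR adjusted p = 0.060) but did with the replicate block (0.024) and without Ddx5 siRNA replicate 1 (0.023) or Ddx5 siRNA plus stress replicate 2 (0.029) or 3 (0.034). Sox9 fell by 0.94 (SE 0.21, edgeR adjusted p = 0.046), a call lost without Ddx5 siRNA replicate 2 (0.25) or 3 (0.14) or Ddx5 siRNA plus stress replicate 1 (0.15) or 2 (0.13). Runx2 did not pass (−0.53, SE 0.13, edgeR adjusted p = 0.065), but passed with the replicate block (0.038) and without Ddx5 siRNA replicate 1 (0.015). The list of immediate early genes, which are induced within minutes of a stimulus, passed with the preset correlation (camera adjusted p = 0.015; adjusted p = 0.97 with an estimated correlation), with 1 of 23 rising, Fosb by 1.70 (4 rose and 1 fell adjusted over the list alone). The Fosb call was lost without Ddx5 siRNA replicate 2 (edgeR adjusted p = 0.057) or Ddx5 siRNA plus stress replicate 2 (0.052). The list call was lost without Ddx5 siRNA replicate 1 (0.97) or Ddx5 siRNA plus stress replicate 2 (0.12) or 3 (0.080).

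In total 169 genes passed for stress in cells with the Ddx5 siRNA, 149 higher and 20 lower. The count was 61 without Ddx5 siRNA replicate 2 and 71 without replicate 3, and 23 when only the 6 libraries compared were fitted. With the replicate number as a block, it was 250, 219 higher and 31 lower, and 985 when only these 6 libraries were fitted with the block, 641 higher and 344 lower (65.1% higher, against 88.2% without). That last fit lost the calls of Mmp3 (edgeR adjusted p = 0.26) and Hk2 (0.17). The pairing is less sure here than without siRNA, as Ddx5 siRNA plus stress replicate 2 correlated best with Ddx5 siRNA replicate 3. Deviations within a group sum to 0, so a deviation shared by both replicate 1 libraries raises the other same-numbered correlations too.

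The responses to stress with and without the Ddx5 siRNA share no library and could be set against each other. Of the 271 genes that passed in either, 266 had the same sign in both. 88 genes rose in both, against 1.58 for independent lists of these sizes, 9 fell in both, against 0.069, and none moved in opposite directions. Across all 14142 genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.49 and Spearman's rho = 0.45, and r was 0.30 without Ddx5 siRNA plus stress replicate 1. In the direct test of the difference between these responses, edgeR called 0 genes (441, or 3.12%, at an unadjusted p under 0.05, smallest adjusted p 0.999), and DESeq2 called 4. That share is smaller than the threshold of 0.05 would give without any difference. The test was thus conservative here, and the 0 calls do not show that the responses are equal. With 1 library left out, edgeR called 1 gene without stress replicate 1 and 2 without stress replicate 3. Icam1 differed by 0.00 (SE 0.16) and Mmp10 by 0.20 (SE 0.31) between the responses, and Nfkbia by 0.61 (SE 0.17). In simulated counts for this test, edgeR recovered 34.3% of genes whose response differed 2-fold and 66.7% of those that differed 4-fold. These counts held no library that stands apart from its group, so the shares may not hold for the real libraries.

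**Figure D3:**
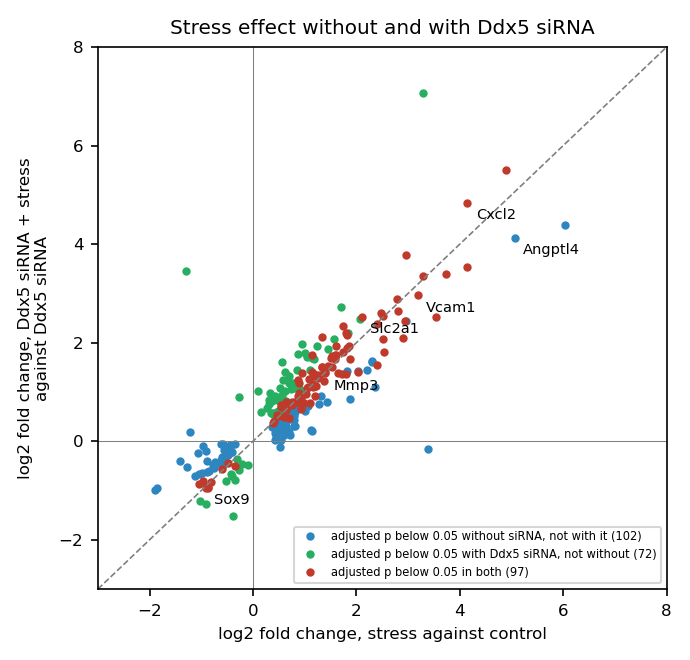
Log2 fold change of stress without siRNA (horizontal axis) and with the Ddx5 siRNA (vertical axis) for genes that passed in either comparison (points, coloured by where they passed). Of the 271 such genes, Slitrk6 (−4.20 without siRNA) and LOC497963 (8.63 with the Ddx5 siRNA) lie beyond the axes and are not shown. Of the 271, 266 have the same sign in both comparisons, and the dashed line marks equal values.

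To see what the Ddx5 siRNA changed without stress, it was compared with the control siRNA. Eln, which encodes elastin, rose from 6.97 ± 3.12 to 28.1 ± 13.8 CPM (log2 fold change 2.01, SE 0.37, edgeR adjusted p = 0.043). Mmp3 rose from 18.9 ± 1.2 to 39.4 ± 6.8 CPM (1.06, SE 0.20, edgeR adjusted p = 0.043) and Mmp10 by 1.34 (SE 0.25), as the only calls among 20 proteases (3 rose adjusted over the list alone; camera adjusted p = 0.57). Both depend on the group they are set against, as the Ddx5 siRNA cells were below the control without siRNA in Mmp3 (−0.54, edgeR adjusted p = 0.39) and Mmp10 (−0.60, 0.42), which did not pass. The genes Btg2, Nov, Eno3, Tspan7, Chchd6, Sars and Dusp1 likewise changed sign against the control without siRNA. The chemokine receptor gene Cxcr4 (chromosome 13, 45314933 to 45318878) was at 2.34 ± 1.86 CPM with the Ddx5 siRNA and 0.090 ± 0.035 CPM with the control siRNA (edgeR adjusted p = 0.037), and the latter is below the 0.21 CPM that 3 counts give.

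Of 23 measured immediate early genes 2 rose, Nr4a1 by 1.30 and the phosphatase gene Dusp1 by 1.02 (11 rose and 1 fell adjusted over the list alone). The list rose with the preset correlation (camera adjusted p = 2.2e-06; adjusted p = 0.46 with an estimated correlation). Its summed CPM in Ddx5 siRNA replicate 1 (1454) lay within the control siRNA libraries (1417 to 1485), below replicates 2 and 3 (2850 and 2709). Protease inhibitors likewise summed to 7058 CPM in replicate 1, 12320 and 12710 in replicates 2 and 3, and 6364 to 6829 with the control siRNA. For inflammatory genes each Ddx5 siRNA library (3463 to 3919 CPM) lay above the control siRNA libraries (2295 to 2600). Inflammatory genes had 0 calls of 28 in edgeR and 6 adjusted over the list alone, with an upward camera call (adjusted p = 2.2e-06; adjusted p = 0.12 with an estimated correlation). All 24 ribosomal protein genes had negative values (median −0.46), 0 passed over all genes and 22 fell adjusted over the list alone (camera adjusted p = 7.6e-14; adjusted p = 0.46 with an estimated correlation). In summed CPM the Ddx5 siRNA group lay nearer to the control without siRNA than to the control siRNA for immediate early genes (2338, 2470 and 1450 in that order). The same held for inflammatory genes (3710, 4094 and 2489) and ribosomal protein genes (13540, 14940 and 18860). Fibroblastic matrix genes lay nearer to the control siRNA on average (103900, 72110 and 125900), but only through Ddx5 siRNA replicate 1 (128600). Replicates 2 and 3 (94810 and 88300) lay nearer to the control without siRNA. All 29 cell cycle genes had positive values (median 0.43) with 0 calls on either count (camera adjusted p = 0.0028; adjusted p = 0.75 with an estimated correlation), a list call lost without Ddx5 siRNA replicate 3 (0.072) or control siRNA replicate 3 (0.096). YAP/TEAD targets and TGF-beta and BMP genes had upward camera calls (adjusted p = 0.0028 for each; adjusted p = 0.46 with an estimated correlation) with 0 edgeR calls over all genes, and 4 each adjusted over the list alone. Protease inhibitors also had an upward camera call (adjusted p = 0.0048; adjusted p = 0.46 with an estimated correlation) with 0 calls of 9 and 4 adjusted over the list alone. Fibroblastic matrix genes had a downward one (camera adjusted p = 0.011; adjusted p = 0.64 with an estimated correlation), although their only edgeR call, Eln, rose. That list call was lost without Ddx5 siRNA replicate 2 (0.053) or 3 (0.12).

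Of the genes that fell, the aldehyde dehydrogenase gene Aldh3a1 went from 53.9 ± 7.4 to 19.1 ± 4.4 CPM (−1.50, SE 0.29), and Ykt6, which encodes a membrane fusion protein (chromosome 14, 86195892 to 86205712), from 89.3 ± 4.2 to 58.1 ± 6.8 CPM (−0.62, SE 0.10). Sox9 did not pass (0.40, SE 0.21), nor did Acan (0.03, SE 0.38) or Timp1, a metalloproteinase inhibitor gene (0.58, SE 0.19). In total 56 genes passed for the Ddx5 siRNA, 33 higher and 23 lower (58.9% higher), against 10 higher and 14 lower (41.7% higher) in limma on log2(FPKM + 1). The count was 1 without Ddx5 siRNA replicate 2 or 3 or control siRNA replicate 1 or 3, 2 without control siRNA replicate 2 and 645 without Ddx5 siRNA replicate 1, so that each call named here for the Ddx5 siRNA was lost without any 1 of the first 5 libraries (edgeR adjusted p up to 0.29). The call that remained throughout, chosen for mention after its values were seen, was Cgnl1, a junction protein gene that rose from 19.1 ± 1.0 to 42.3 ± 2.5 CPM (1.14, SE 0.11, edgeR adjusted p = 0.00032). Against the control without siRNA 3 genes passed, Ddx5, Cgnl1 (0.83) and the amino acid transporter gene Slc7a5 (0.88).

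Under stress, the Ddx5 siRNA was set against stress without siRNA, so this comparison holds the effect of transfection too. Besides Ddx5, the genes that fell were Ykt6 and Retsat. Ykt6 fell by 0.68 (SE 0.10) and Retsat, a retinol saturase gene, by 0.48 (SE 0.07), both with edgeR adjusted p = 0.038. Ddx5 and Ykt6 thus fell under the Ddx5 siRNA both with and without stress. Mmp3, at 150 ± 15 CPM with stress and 103 ± 35 CPM with stress and the Ddx5 siRNA, did not pass, nor did Sox9 (0.05, SE 0.22) or Acan (1.03, SE 0.38, edgeR adjusted p = 0.35). The 20 proteases had a median log2 fold change of 0.13 and a mean of 0.08, against a downward camera direction that did not pass (adjusted p = 0.93).

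Of 22 cholesterol synthesis genes, 21 had positive values (median 0.46) and 4 rose adjusted over the list alone (camera adjusted p = 0.00023; adjusted p = 0.91 with an estimated correlation), a list call lost without Ddx5 siRNA plus stress replicate 1 (0.44). Fibroblastic matrix genes (18 of 20 positive, camera adjusted p = 0.0079), mechanosensors (15 of 18, 0.012), YAP/TEAD targets (18 of 20, 0.014) and cell cycle genes (29 of 29, 0.029) had upward list calls with 0 edgeR calls over all genes. Each had adjusted p = 0.91 with an estimated correlation. Ribosomal protein genes had a downward one (22 of 24 negative, camera adjusted p = 0.012; adjusted p = 0.91 with an estimated correlation), and Schwann cell and neuron markers an upward one (6 of 6, 0.029; adjusted p = 0.56 with an estimated correlation). Leaving out 1 library ended each of these list calls. Without stress replicate 3 the adjusted p was 0.11 for fibroblastic matrix, 0.23 for mechanosensors, 0.98 for cell cycle, 0.20 for ribosomal proteins and 0.092 for the neural markers. Without Ddx5 siRNA plus stress replicate 1 it was 0.43 for fibroblastic matrix, 0.064 for mechanosensors and 0.14 for the neural markers, without replicate 2 it was 0.075 for YAP/TEAD, 0.36 for cell cycle and 0.45 for ribosomal proteins, and without replicate 3 it was 0.14, 0.72 and 0.22 for these. Without stress replicate 1 it was 0.072 for YAP/TEAD targets and for ribosomal proteins, and without stress replicate 2 it was 0.18 for the neural markers.

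In total 4 genes passed for the Ddx5 siRNA under stress, 1 higher and 3 lower (25% higher), against 18, 8 higher and 10 lower (44.4% higher), with RLE scaling and 0 when only the 6 libraries compared were fitted in edgeR. In limma on log2(FPKM + 1), 0 were higher and 4 lower. The count was 7 without stress replicate 2, 0 without stress replicate 3 or Ddx5 siRNA plus stress replicate 3, and 1 without Ddx5 siRNA plus stress replicate 1 or 2, and the Retsat call was lost with any of the 6 libraries left out (edgeR adjusted p up to 0.17). The Ykt6 call was lost without all but stress replicate 1 (up to 0.17).

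Of the 58 genes that passed for the Ddx5 siRNA in either setting, which share no library, 45 had the same sign in both. Across all 14142 genes the log2 fold changes correlated with r = 0.10 and rho = 0.21, and r was 0.060 without Ddx5 siRNA replicate 1, 0.17, 0.041 and 0.037 without Ddx5 siRNA plus stress replicates 1, 2 and 3. In the direct test of the difference between these effects, edgeR called 0 genes (1179 at an unadjusted p under 0.05, smallest adjusted p 0.066), DESeq2 called 114 and edgeR without Ddx5 siRNA replicate 1 called 44. edgeR called 1 without stress replicate 1 or Ddx5 siRNA plus stress replicate 1. Mmp3 differed by −1.60 (SE 0.27) between the settings, which did not pass over all genes in edgeR (adjusted p = 0.090) but did without Ddx5 siRNA replicate 1 (adjusted p = 0.029) or Ddx5 siRNA plus stress replicate 1 (0.00091). Because the settings use different references, this difference is the difference of the stress effects plus that of control siRNA against control. For Mmp3 the former was −0.0066, so nearly all of the −1.60 is the difference between control siRNA and control.

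The control siRNA was compared with the control without siRNA, which gives the background against which the Ddx5 siRNA is read. Asns, which encodes asparagine synthetase (chromosome 4, 33743364 to 33761163), rose from 67.1 ± 17.7 to 183 ± 8.1 CPM (log2 fold change 1.45, SE 0.18, edgeR adjusted p = 0.00090). Phgdh, which encodes the first enzyme of serine synthesis, rose by 1.51 (SE 0.27), and the cationic amino acid transporter gene Slc7a3 by 3.38 (SE 0.51). Of the 22 genes of the unfolded protein and integrated stress response, 8 rose and 2 fell (10 rose and 5 fell adjusted over the list alone). The transcription factor gene Atf5 rose by 1.72 (SE 0.23), and Slc7a11, which encodes a cystine transporter, by 1.72 (SE 0.35), the latter a call lost without control siRNA replicate 1 (edgeR adjusted p = 0.066) or 3 (0.056). The 2 members that fell were the endoplasmic reticulum chaperone genes Dnajb9 (by 0.76) and Creld2 (by 0.61). The Dnajb9 call was lost with any of the 6 libraries left out (0.051 without control replicate 2 to 0.13 without control siRNA replicate 3) and the Creld2 call without control replicate 1 (0.082) or 3 (0.16) or control siRNA replicate 1 (0.10), 2 (0.11) or 3 (0.15). The list passed with the preset correlation (camera adjusted p = 0.037; adjusted p = 0.42 with an estimated correlation), and was lost without control replicate 2 (0.096) or control siRNA replicate 1 (0.055).

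Inflammatory and immediate early genes had downward list calls with the control siRNA, and fibroblastic matrix genes an upward one, each with the preset correlation. Of 28 inflammatory genes 7 fell and none rose (10 fell adjusted over the list alone; camera adjusted p = 7.8e-07; adjusted p = 0.087 with an estimated correlation), Icam1 by 0.66 and Nfkbia by 0.85. Of 23 immediate early genes 5 fell and 1 rose (12 fell and 1 rose adjusted over the list alone), Fos by 2.96 (SE 0.52) and Dusp1 by 1.17 (camera adjusted p = 7.0e-06; adjusted p = 0.42 with an estimated correlation). The Fos call was lost without control siRNA replicate 1 or 2 (edgeR adjusted p = 0.061 for each). Mmp3 fell by 1.59 (SE 0.20), from 57.1 ± 7.7 to 18.9 ± 1.2 CPM, and Mmp10 by 1.94 (SE 0.25). The 20 proteases, of which 1 rose and 3 fell, had a median of 0.15, a mean of −0.05 and an upward camera direction that did not pass (adjusted p = 0.94). Of 20 fibroblastic matrix genes 6 rose and none fell (12 adjusted over the list alone; camera adjusted p = 2.7e-07; adjusted p = 0.42 with an estimated correlation). Among them, Col1a1, which encodes a chain of type I collagen and is the most abundant gene, rose by 0.91 (SE 0.20), from between 3.17% and 3.82% of all counts in the control libraries to between 5.46% and 6.91% with the control siRNA. The Col1a1 call was lost without control replicate 1 (edgeR adjusted p = 0.089) or 3 (0.068) or control siRNA replicate 2 (0.075) or 3 (0.099).

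TGF-beta and BMP genes (7 of 24 fell, 9 adjusted over the list alone) and protease inhibitors (3 of 9 fell, 5 adjusted over the list alone) had downward list calls (camera adjusted p = 0.0051 and 0.0053; adjusted p = 0.42 with an estimated correlation for both). Among the latter Timp1 fell by 0.82 (SE 0.19), a call lost with any of the 6 libraries left out (edgeR adjusted p from 0.055 without control replicate 2 to 0.11 without control siRNA replicate 1). All 24 ribosomal protein genes had positive values (camera adjusted p = 2.7e-06; adjusted p = 0.42 with an estimated correlation) with 0 edgeR calls on either count. DEAD-box helicase genes had a downward list call with 1 higher and 2 lower of 22 (1 and 3 adjusted over the list alone; camera adjusted p = 0.0051; adjusted p = 0.42 with an estimated correlation). Mechanosensors (3 higher and 2 lower of 18; 0.015), cholesterol synthesis (0.012), glycolysis and hypoxia (0.027) and mitochondrially encoded genes (0.039) had upward and splicing factors (0.027) downward camera calls, none of which held with an estimated correlation (adjusted p from 0.42 to 0.65 with an estimated correlation). Leaving out control replicate 1 ended the call for splicing factors (0.11) and mitochondrial genes (0.17), control replicate 2 those for cholesterol (0.073), glycolysis (0.083) and mitochondrial genes (0.096), and control replicate 3 those for mechanosensors (0.068) and glycolysis (0.064). Leaving out control siRNA replicate 1 ended it for glycolysis (0.069) and mitochondrial genes (0.055), and replicate 3 for splicing factors (0.082) and mitochondrial genes (0.067).

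In total 547 genes passed between control siRNA and control, 297 higher and 250 lower, the highest number of the 5 comparisons between single groups in the fit of all 15 libraries. The count was 206 without control replicate 1, 177 without control replicate 3, and 166, 171 and 190 without control siRNA replicates 1, 2 and 3.

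Along the direction set by these 547 genes, scaled so that the control libraries average 0 and the control siRNA libraries 1, the Ddx5 siRNA libraries stood apart from each other. Ddx5 siRNA replicate 1 lay at 0.67 and replicates 2 and 3 at 0.29 each, and with stress replicate 1 lay at 0.60 and the other two at 0.27 each. The stress libraries without siRNA lay between 0.02 and 0.22. Without both replicate 1 libraries of the Ddx5 siRNA, a setting chosen after their position was seen, 1915 genes passed for the Ddx5 siRNA, 160 for the Ddx5 siRNA under stress, 142 for the difference between these effects, 868 for stress, 148 for stress in cells with the Ddx5 siRNA and 1804 for the control siRNA.

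**Figure D4:**
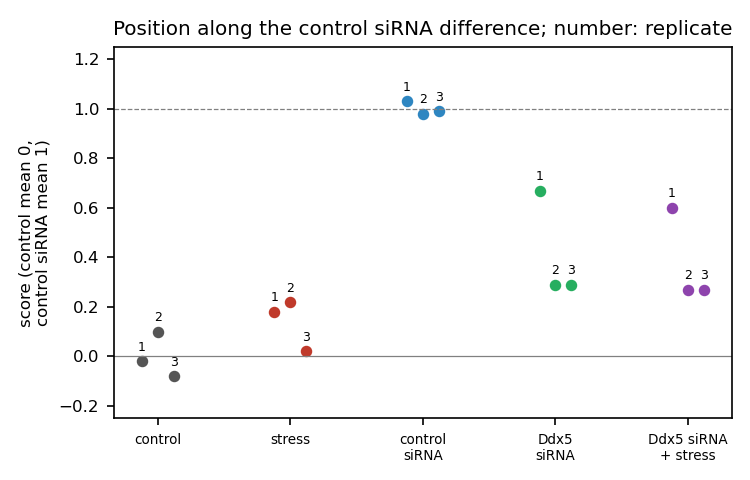
Score of each of the 15 libraries (points, by group) along the direction from the control to the control siRNA libraries over the 547 genes called between them, scaled so that the control group averages 0 and the control siRNA group 1. The replicate 1 libraries of both Ddx5 siRNA groups (0.67 and 0.60) lie above replicates 2 and 3 of the same groups (0.27 to 0.29).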

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

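The tests of the control siRNA as a source of calls, of an equal effect with and without stress, of counts taken by a few genes, of a mislabelled library, of a batch shared by replicate 1 and, in part, of depth were chosen after the result they measure was seen, and the other tests of this part before.

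For 9 gene lists the effect of the Ddx5 siRNA with and without stress had a camera call in the test of the difference itself with the preset correlation, adjusted over 27 lists. None of the 9 held with an estimated correlation, where the adjusted p was 0.26 for inflammatory genes and for p53 and senescence genes, and 0.57 for the others. In a refit of the 12 libraries alone the real split called 7 lists, and 36 of 100 splits, the real one included, called at least as many. These splits mix effects of stress and of siRNA, so that share does not measure chance. Each comparison was made against another kind of control, stress without siRNA in one case and the control siRNA in the other. The difference therefore equals that of the stress effects plus that of control siRNA against control. By itself it cannot show an effect of the Ddx5 siRNA that depends on stress. Control siRNA against control had list calls in the same direction for fibroblastic matrix, cholesterol, ribosomal protein, inflammatory, protease inhibitor, immediate early and mechanosensor genes. It had none for the p53 and cartilage matrix lists. Relative to the effect without stress, the effect under stress was higher for fibroblastic matrix genes (adjusted p = 9.2e-06, median difference 0.59 on the log2 scale), cholesterol synthesis genes (adjusted p = 9.2e-06, 0.61) and ribosomal protein genes (adjusted p = 9.2e-06, 0.34). It was lower for inflammatory genes (adjusted p = 0.00061, −0.53). These 4 calls were kept with each of the 12 libraries left out. Protease inhibitors (adjusted p = 0.014, −0.60) and immediate early genes (adjusted p = 0.014, −0.29) were lower. The former call was lost without Ddx5 siRNA replicate 2 (0.062), Ddx5 siRNA plus stress replicate 1 (0.051) or control siRNA replicate 1 (0.051), and the latter without Ddx5 siRNA replicate 2 (0.094) or 3 (0.10) or Ddx5 siRNA plus stress replicate 1 (0.070). Mechanosensors (adjusted p = 0.034, 0.24) and p53 and senescence genes (adjusted p = 0.034, 0.30) were higher. The mechanosensor call was lost without stress replicate 3 (0.22), Ddx5 siRNA replicate 2 (0.067), Ddx5 siRNA plus stress replicate 1 (0.051) or 3 (0.077) or control siRNA replicate 1 (0.067), and the p53 call without stress replicate 1 (0.059) or 2 (0.067), Ddx5 siRNA replicate 1 (0.081), Ddx5 siRNA plus stress replicate 1 (0.051) or control siRNA replicate 1 (0.054). Cartilage matrix genes were lower (adjusted p = 0.0497, −0.35), a call lost without stress replicate 1 (0.11) or 2 (0.064), Ddx5 siRNA replicate 2 (0.23), Ddx5 siRNA plus stress replicate 1 (0.070) or 3 (0.097) or control siRNA replicate 1 (0.22).

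With the preset correlation, the stress effect with and without the Ddx5 siRNA had a camera call of the difference for 3 lists, none of which held with an estimated one (adjusted p = 0.94 for each). In a refit of the 12 libraries alone the real split called 2 lists, and 92 of 100 splits, the real one included, called at least as many. Here too the splits mix effects of stress and of siRNA, so that share does not measure chance. Each of the 3 lists was higher with the Ddx5 siRNA: splicing factors (adjusted p = 0.0085, median difference 0.18), immediate early genes (adjusted p = 0.032, 0.31) and cholesterol synthesis genes (adjusted p = 0.037, 0.17). The splicing call was lost without stress replicate 2 (0.055), Ddx5 siRNA replicate 1 (0.067) or Ddx5 siRNA plus stress replicate 3 (0.11). The immediate early call was lost without control replicate 3 (0.18), stress replicate 2 (0.12), Ddx5 siRNA replicate 1 (0.93) or Ddx5 siRNA plus stress replicate 2 (0.099) or 3 (0.11). The cholesterol call was lost without control replicate 1 (0.20) or 3 (0.083), stress replicate 2 (0.39), Ddx5 siRNA replicate 2 (0.35) or 3 (0.33) or Ddx5 siRNA plus stress replicate 1 (0.89).

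The genes called between the Ddx5 siRNA and the control siRNA had small log2 fold changes against the control without siRNA. Over the 55 called genes other than Ddx5, the median ratio of the log2 fold change against the control to that against the control siRNA was 0.09 (bootstrap 95% interval −0.04 to 0.25), a value that a shift of the control siRNA libraries needs, although picking genes by their distance from the control siRNA lowers this ratio by itself. An equal effect of the Ddx5 siRNA with and without stress stays open. The median ratio of the effect under stress to that without was 0.24 (0.08 to 0.31), but it decides nothing, as the reference under stress was without siRNA, which adds transfection to the effect. Counts taken by a few genes are argued against, since the 10 most abundant genes held between 10.8% and 15.1% of the counts in the 9 libraries of these groups, which shifts every other gene by at most 0.07 on the log2 scale, below the smallest change of the 55 genes (0.42). What stays open is whether the control siRNA, the Ddx5 siRNA, both, or a shift of the control siRNA libraries from another source moved these genes. No group with the control siRNA and stress was among the samples to help tell these apart.

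Replicate 1 of both Ddx5 siRNA groups lay nearer to the control siRNA libraries (scores of 0.67 and 0.60) than replicates 2 and 3 (0.27 to 0.29). Mislabelled control siRNA libraries are argued against, since the higher Ddx5 level of the pair was 220.6 CPM, below the lowest control siRNA library at 360 CPM. Depth is argued against, since Ddx5 siRNA replicate 1 had 15684140 counts and a library within 0.32% of that total scored 0.27, while Ddx5 siRNA plus stress replicate 1, whose total is slightly above that of any other library, had a partner within 0.15% that scored 0.29. A batch shared by all libraries numbered 1 stays open, since their deviations from the group means correlated over 0.1 in 6 of the 10 pairs of groups, those without the control siRNA (0.22 to 0.59), but at −0.11 to 0.07 in the 4 with it. A batch or a stronger transfection shared by these 2 libraries alone stays open too, and no biological explanation was tested.

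Glycolysis and hypoxia genes had upward list calls under stress with and without the Ddx5 siRNA with the preset correlation, and not with an estimated one (adjusted p = 0.35 without and 0.33 with the Ddx5 siRNA). A single library as the source is argued against, since the highest camera adjusted p with the preset correlation and any library of either comparison left out was 2.1e-16. Cultures that vary in these genes whatever their group, for example in density or oxygen supply, remain a candidate explanation. The smallest difference in the list's median between a stressed and an unstressed library of the same siRNA status was 0.14 on the log2 scale, less than the largest difference within a group (1.08, among the Ddx5 siRNA plus stress libraries), although all 18 such differences were above 0. Both values come from the Ddx5 siRNA libraries, and the 0.14 sets stressed replicate 2 against unstressed replicate 1. By number, the stressed and unstressed centred medians there were 1.22 and 0, 0.14 and −0.38, and 0.50 and −0.37. Without siRNA they were −0.53 to −0.36 in the control and 0.32 to 0.52 under stress. That gap is wider than either group's spread. It would argue against this explanation for those libraries only if each came from its own culture, which the labels do not say. For the inflammatory list the smallest difference was 0.70 and the largest within a group 0.49, and an effect of stress on both lists stays open too.

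Other splits of the same libraries were refitted, with only the libraries of the comparison and without the block. For the 5 comparisons of 3 libraries with 3 there are 10 splits, too few for a share under 0.05. For stress, where the numbers pair the libraries, the real split called 202 genes and the highest of the other splits that part all 3 pairs, 3 in all, called 1, as did the highest of the others, which part 1 pair only. For stress in cells with the Ddx5 siRNA these values were 23, 0 and 2. The real split called 39 genes for the Ddx5 siRNA (highest other 2), 0 for the Ddx5 siRNA under stress (highest other 2) and 1394 for the control siRNA (highest other 3). A count as large as the real one came from 1 of the 10 splits in each of these comparisons except the Ddx5 siRNA under stress, where all 10 gave it. For lists, the real split called 5 for stress (highest other 10, or 3 among splits that part all pairs; 5 of 10 splits as many), 3 for stress in cells with the Ddx5 siRNA (highest other 10, or 3 among splits that part all pairs; 8 of 10), 9 for the Ddx5 siRNA (highest other 13; 4 of 10), 7 for the Ddx5 siRNA under stress (highest other 10; 3 of 10) and 11 for the control siRNA (highest other 7; 1 of 10).

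For the differences of effects 100 splits of 12 libraries were compared, the real split included. The real split called 0 genes in both, a count that all 100 splits reach by construction, as do all 10 for the Ddx5 siRNA under stress, so these shares say nothing about chance. The highest other split called 2 genes for the difference of stress effects and 921 for that of Ddx5 siRNA effects, and the latter points to a structure of the samples, whose source was not tested. For lists, 92 of 100 splits gave as many as the 2 called for the difference of stress effects (highest other 12). For that of Ddx5 siRNA effects, 36 of 100 gave as many as the 7 called (highest other 12). These splits moved libraries freely across the groups, so effects of stress and of siRNA enter them. They cannot show how many lists a difference of effects would call by chance, and chance was not excluded.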

How the results depend on the processing

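The settings without both replicate 1 libraries of the Ddx5 siRNA, with the control in place of the control siRNA, with only the groups compared and the block together, without the 10 most abundant genes, and with libraries left out of the list tests and the Ddx5 level were chosen after the data were seen, so the first is no independent evidence, and the others had been fixed earlier.

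The cause of the changes in counts of called genes was not tested except where fewer libraries or more tested genes enter by construction. Stress and the control siRNA were each set against the control, and neither comparison holds a Ddx5 siRNA library. Their rises without both replicate 1 libraries, from 199 and 547, can thus come only through the spread, scaling and filter that all libraries share. What each of these added was not tested. DESeq2 called 535 genes for stress, 352 for stress with the Ddx5 siRNA, 385 for the Ddx5 siRNA, 156 for it under stress, 1059 for the control siRNA, and 4 and 114 for the differences of stress and of Ddx5 siRNA effects. On log2(FPKM + 1) with no filter on low values, limma called 122, 108, 2, 7, 312, 1 and 1 in the same order, and with the filter it called 24 for the Ddx5 siRNA with either pseudocount. RLE scaling gave 18 and no filter on low counts 16 for the Ddx5 siRNA under stress. Fits of only the groups compared gave 23 for stress with the Ddx5 siRNA, 0 for the Ddx5 siRNA under stress and 1394 for the control siRNA. Without both replicate 1 libraries the counts were 868 for stress, 1915 for the Ddx5 siRNA, 160 for it under stress, 142 for the difference of Ddx5 siRNA effects and 1804 for the control siRNA, and the preset genes had 30 calls in place of 12 over the 7 comparisons, against 7 in limma on log2(FPKM + 1) and 5 without its filter. Leaving out both replicate 1 libraries added calls of Ddx5, Adamts4 and Timp1 for stress, of Adamts4, Timp1, Col2a1, Sox9, Col1a1 and Ptgs2 for the Ddx5 siRNA, of Mmp3 for it under stress, of Mmp13 and Runx2 for stress with the Ddx5 siRNA, of Mmp3 and Timp1 for the difference of Ddx5 siRNA effects, and of Ddx5, Adamts4, Col2a1 and Ptgs2 for the control siRNA. Against the control in place of the control siRNA, 3 genes were called.

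With the replicate number as a block, 366 genes were called for stress, 417 for the Ddx5 siRNA (181 higher, 236 lower), 30 for it under stress, 1174 for the control siRNA, 26 for the difference of Ddx5 siRNA effects, 250 for stress with the Ddx5 siRNA and 0 for the difference of stress effects. With the block and only the groups compared, the counts were 1682 for stress and 985 for stress with the Ddx5 siRNA. That fit added Ddx5, Adamts4, Adamts5, Timp1, Acan and Ptgs2 for stress and Mmp13, Acan, Runx2 and Il6 for stress with the Ddx5 siRNA, and there lost Mmp3, Hk2, Hilpda, Ccl2, Ccl7 and Slc2a1. Same-numbered libraries correlated at −0.18 to 0.02 for the Ddx5 siRNA, 0.05 to 0.30 for it under stress, 0.07 to 0.09 for the control siRNA, 0.03 to 0.59 for the difference of stress effects and −0.18 to 0.59 for that of Ddx5 siRNA effects, so not all pairs in these exceeded 0.1. The pairs of stressed with unstressed libraries of the same siRNA status did. Those with the Ddx5 siRNA enter both differences, and those without siRNA the difference of stress effects. Each library correlated best with its own number in 3 of 3 pairs for the control siRNA, 1 of 3 for the Ddx5 siRNA and 2 of 3 for it under stress. For stress this held in 3 of 3 pairs, and for stress with the Ddx5 siRNA in 2 of 3. Among lists the block added cholesterol synthesis under stress (adjusted p = 0.025) and TGF-beta and BMP genes in the difference of stress effects (0.017), and it changed no other list call. Among named genes it added Mmp13 (0.024) and Runx2 (0.038) for stress with the Ddx5 siRNA, Ddx17 (0.041) for the Ddx5 siRNA, and Ddx5 (0.032) and Col2a1 (0.036) for the control siRNA, and the block in the fit of all libraries changed no other call of a named gene.

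With 1 library left out at a time, the counts ran from 81 to 157 for stress, 61 to 187 for stress with the Ddx5 siRNA, 1 to 645 for the Ddx5 siRNA, 0 to 7 for it under stress, 166 to 392 for the control siRNA, 0 to 2 for the difference of stress effects and 0 to 44 for that of Ddx5 siRNA effects. Called lists, 47 over all comparisons, ran from 39 to 52, and 2 held with an estimated correlation, the inflammatory list in both stress comparisons. Ddx5 stood at 55.5% to 61.3% of the control siRNA level, and at 58.9% in FPKM. The correlation of both stress effects, r = 0.49, was 0.87 over genes called in either, 0.40 without both replicate 1 libraries, and 0.30 to 0.49 with 1 library left out. That of both Ddx5 siRNA effects, r = 0.10, was 0.65, 0.29 and 0.037 to 0.17.

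Signs turned for 13 named genes, of which 9 were called in either fit, when the Ddx5 siRNA was set against the control in place of the control siRNA: log2 fold changes became −0.54 for Mmp3, −0.60 for Mmp10, −0.057 for Btg2, −0.43 for Nov, −0.15 for Dusp1, 0.12 for Eno3, 0.045 for Tspan7, 0.12 for Chchd6 and 0.31 for Sars, and, called in neither fit, 0.94 for Adamts4, −0.25 for Timp1, 0.64 for Col1a1 and 0.021 for Runx2. None of these passed against the control. Of the stress calls named in the report, limma on log2(FPKM + 1) lost those of Mmp13, Sox9, Runx2, Adamts1 and Myh1, and a fit of only the groups compared those of Runx2, Adamts1, Angptl4, Ccl5, Piezo1, Srsf6 and Myh1. Of the Ddx5 siRNA calls named there, the former lost those of Mmp3, Mmp10, Eln, Cxcr4, Nr4a1, Btg2, Nov, Eno3, Sars and Aldh3a1, and the latter those of Mmp10, Eln, Btg2, Nov, Eno3, Tspan7, Chchd6, Sars, Dusp1 and Ykt6. The glycolysis and hypoxia list, not called for the Ddx5 siRNA under stress, was called downward without both replicate 1 libraries (camera adjusted p = 0.0019). Of 4900 values for named genes under the alternatives, 3773 kept their direction and side of the threshold, 105 changed sign without a call in either fit, 961 lost the call, 52 gained it and 9 reversed. Of 567 for lists these were 477, 26, 54, 9 and 1. At 14309170 to 16219912 counts per library, a gene with 3 counts lies at 0.21 CPM.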

Other observations

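The tests on aminoacyl-tRNA synthetase genes, and their list itself, were chosen after the data were seen, although the prediction for the Ddx5 siRNA under stress was written before that result.

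Spry1, an inhibitor of receptor tyrosine kinase signalling, fell with stress, by 0.86 (SE 0.14, edgeR adjusted p = 0.0052) without siRNA and by 0.95 (SE 0.14, edgeR adjusted p = 0.0030) with the Ddx5 siRNA, there with any of the 6 libraries left out as well. Cdkn2b, which encodes an inhibitor of cyclin-dependent kinases, fell from 139 ± 6.4 to 83.1 ± 10.7 CPM under stress (SD, n = 3; log2 fold change −0.74, SE 0.10, edgeR adjusted p = 0.0018), and was at −0.43 (SE 0.10, edgeR adjusted p = 0.060) with the Ddx5 siRNA, which did not pass. Scx, a transcription factor gene of tendon and its attachment, fell with stress in cells with the Ddx5 siRNA (−0.67, SE 0.12, edgeR adjusted p = 0.011), a call lost without Ddx5 siRNA replicate 2 (0.080).

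With the control siRNA, Spp1, which encodes the bone matrix protein osteopontin, rose from 793 ± 146 to 1867 ± 244 CPM (log2 fold change 1.23, SE 0.18, edgeR adjusted p = 0.0019), with any of the 6 libraries left out as well. Sp7, which encodes the osteoblast factor osterix, fell by 2.11 (SE 0.47), a call lost without control replicate 1 (edgeR adjusted p = 0.052), 2 (0.057) or 3 (0.091) or control siRNA replicate 1 (0.12) or 3 (0.11). Adm2, which encodes a peptide of the calcitonin family, rose from 1.20 ± 0.85 to 11.6 ± 1.5 CPM. Of 21 interferon response genes, which can respond to transfected RNA, 0 were called in edgeR over all genes and 1 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.057 downward; adjusted p = 0.42 with an estimated correlation).

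Aminoacyl-tRNA synthetase genes, whose products load amino acids onto tRNA, were higher with the control siRNA. Of 20 tested, 13 rose and 17 had positive values, with a median log2 fold change of 0.62 (camera p = 2.9e-16, and p = 0.00027 with an estimated correlation), and the highest value was 1.03 for Yars (SE 0.09). The hypothesis was that this rise may come with siRNA transfection as such, in which case it should be seen in the Ddx5 siRNA under stress against stress without siRNA, which shares no library with the first comparison. There, 15 of 20 had positive values with a median of 0.18 and 0 edgeR calls, and the list was higher (camera p = 0.00040, and p = 0.040 with an estimated correlation). The first p stayed between 0.00014 and 0.0049 with each of the 6 libraries left out, while the latter rose to between 0.068 and 0.090 with any left out except stress replicate 3. In the Ddx5 siRNA group without stress, 15 of 20 values were positive against the control (median 0.28, p = 0.0021 with an estimated correlation) and 1 of 20 against the control siRNA (median −0.31), in comparisons that share libraries with the first. A rise that depends on the siRNA sequence or on the strength of transfection in each group stays open.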
